A study of Homo sapiens with 2 samples.

How the data were processed

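RNA sequencing was carried out on 2 libraries of a human cell line that the labels call SH-SY5Y, a line derived from a neuroblastoma and widely used as a neuron-like model in toxicology. One library came from control cells and 1 from cells exposed for 24 h to a mixture of TDCPP, the chlorinated organophosphate flame retardant tris(1,3-dichloro-2-propyl) phosphate, and titanium dioxide nanoparticles. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy kit and libraries were made with a SMARTer messenger RNA kit. The labels describe no library of either agent alone, no dose and no replicate, so the contrast is that of the mixture against the control, with 1 library on each side.

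The deposited table holds 1 FPKM value (fragments per kilobase of gene length, scaled to library size) per gene and library for 58735 genes. The aligner and the counting tool are not given in the sources used here. The submitters' processing notes name the mouse builds GRCm38 and mm10, whereas every one of the 58735 gene identifiers in the deposited table is a human Ensembl identifier. All 58735 had the symbol, the start and the end given in GENCODE release 29 (Ensembl release 94, GRCh38), and the deposited gene length equalled the summed length of the merged exons for 100% of them. Coordinates are therefore given on GRCh38. The table carries no statement on strand, so reads of a gene and of an antisense partner cannot be told apart, and reads of near-identical copies may have been assigned to either copy.

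The whole reads behind the deposited FPKM values were recovered from the file. The product of FPKM and gene length was a whole multiple of 1 step within each library, within a tolerance of 0.001 reads, for 100% of the 26842 values above 0 in the control library and of the 27007 in the exposed library. The sums were 16471438 reads for the control and 15315572 reads for the exposed library. The library totals used in the deposited FPKM equalled these sums multiplied by 0.971 and 1.03. These are the median-of-ratios size factors of the 2 read vectors, taken relative to library size. The authors' values were therefore already scaled between the libraries and no further scaling was applied. Intervals printed beside ratios are exact conditional binomial (Clopper-Pearson) 95% intervals of the read ratio, and those beside shares of reads are Wilson 95% intervals. They cover counting error only, compare these 2 libraries and not the conditions, and treat reads as independent although no molecular identifiers were used here.

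The expression difference was log2((exposed FPKM + 1)/(control FPKM + 1)), called the log2 ratio, with a pseudocount of 1, which understates the difference of genes with low values. Measured genes were the 11409 protein-coding genes with a mean FPKM of 1 or more over both libraries. With 1 library per group no test across genes was run and no p-value is given. Genes were counted by a fixed rule of size, a log2 ratio of at least 1 in either direction. For each of 42 gene lists, the median log2 ratio of the measured members was placed among 10000 random lists of the same size drawn from 20 bins of mean expression, and the list was said to stand apart at or under the 2.5th or at or over the 97.5th percentile, as a description of these libraries. Of 959 list entries, 956 were found in the table. Named genes were the 12 highest and the 12 lowest log2 ratios among protein-coding genes with a mean FPKM of 5 or more, every measured gene of the mitochondrial fission and the mitochondrial fusion and cristae lists, and the up to 4 members with the largest absolute log2 ratio of every other list. The size rule, the lists, the naming rule and the first group of alternative settings below were fixed before the data were examined. Other genes named as examples were chosen after their values were seen, and 8 further lists added at that stage are marked as such. A few genes that these rules cover are not reported here.

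The procedure was tested on simulated reads drawn for 11415 genes at the means and depths of these libraries. The size rule recovered 80 of 100 genes simulated at 2.5-fold and 98 of 100 simulated at 4-fold, and 1 of 11215 unchanged genes passed it by counting noise. For lists of 20 genes, 3 of 100 unchanged lists stood apart, as did 100 of 100 lists shifted by 0.30 in log2 ratio. In these simulations unchanged genes varied independently and by counting noise only. The list rates therefore do not cover the wider spread of the real log2 ratios or lists whose genes move together.

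Alternative settings were pseudocounts of 0.1 and 5, no filter on low values, a mean FPKM of at least 5, equal FPKM sums (TPM), a trimmed mean of log ratios set to 0, equal 75th percentiles, scaling without the 100 most abundant and the mitochondrially encoded genes, all gene classes in place of protein-coding genes, thresholds of 1.5-fold and 3-fold, and random lists that were unmatched or matched on gene length too. Removal of a trend on GC content and gene length, comparison of the mitochondrially encoded list with the 100 most abundant nuclear genes, and removal of genes shared between lists were added after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.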

Results

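Gene expression was measured by RNA sequencing in 1 control library and 1 library of cells exposed for 24 h to TDCPP and titanium dioxide nanoparticles together. The libraries held 16471438 and 15315572 reads on annotated genes, and 11409 protein-coding genes reached a mean FPKM of 1. The series title names apoptosis and the balance of mitochondrial division and fusion, so the comparison asks how genes of these processes, and the transcriptome around them, differed between exposed and control cells. There were no replicates, so no difference below has a replicate check, and intervals cover counting error only.

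Among genes with a mean FPKM of at least 5, GDF15, TRIB3 and DDIT3 had the highest log2 ratios of FPKM with a pseudocount of 1. Genes of the integrated stress response and of the p53 pathway were higher as groups, whereas genes of the G2/M phase, heat shock proteins, cholesterol synthesis and the messenger RNAs of the mitochondrial genome were lower as groups. Genes of mitochondrial fission and fusion differed little, and no measured member of either list reached 1.5-fold. Genes were counted by the same log2 ratio, while ratios printed with an interval are read ratios without it. Of the 11409 measured genes, 75 were at least 2-fold higher and 15 at least 2-fold lower, together 0.789% of them. These counts depended on the pseudocount and the threshold, with 132 higher and 54 lower at a pseudocount of 0.1, 38 and 1 (HSPA1B) at a pseudocount of 5, and 289 and 247 at 1.5-fold. The counting interval of the read ratio excluded 1 for all 90 genes at least 2-fold apart with a pseudocount of 1. The median log2 ratio of all measured genes was -0.05, the middle 95% lay between -0.56 and 0.59, and across genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) between the libraries was 0.978.

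GDF15, a secreted stress cytokine (ENSG00000130513, chromosome 19, 18374731 to 18389176), stood at 1.02 FPKM in the control and 54.4 FPKM in the exposed library. Its 34 and 1789 reads gave a ratio of 53.4 (95% counting interval 38.1 to 77.3). TRIB3, a pseudokinase induced downstream of ATF4 (ENSG00000101255, chromosome 20, 362835 to 397559), was 15.5-fold higher (14.1 to 17.1), from 8.23 to 127 FPKM. DDIT3, which encodes the stress transcription factor CHOP (ENSG00000175197, chromosome 12, 57516588 to 57521737), was 10.4-fold higher (8.68 to 12.6), from 6.07 to 63.3 FPKM. The glutathione-degrading enzyme gene CHAC1 was 9.35-fold higher (6.79 to 13.2), AKNA 7.68-fold (6.74 to 8.77), the lysosomal membrane gene LAMP3 6.83-fold (5.71 to 8.23) and the transcription factor gene CEBPB 5.71-fold (5.08 to 6.43). DDIT4, an inhibitor of mTORC1 signalling, was 4.48-fold higher (4.02 to 4.99) and the mitochondrial enzyme gene PCK2 4.39-fold (3.86 to 5.02). PPP1R15A, whose product directs the dephosphorylation of eIF2alpha, was 4.18-fold higher (3.87 to 4.53) and FAM129A 4.14-fold (3.78 to 4.55). The remaining gene of the 12 highest among genes with a mean FPKM of at least 5, EIF3CL (chromosome 16, 28379579 to 28403879), is a near-identical copy of EIF3C (chromosome 16, 28688558 to 28735730), which was among the 12 lowest. EIF3CL had 71 and 910 reads and EIF3C 1190 and 475, and both copies together had 1261 and 1385 reads, a ratio of 1.11 (1.03 to 1.203), so the separate values of either copy are uncertain.

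The 12 lowest log2 ratios of the same genes reached -1.44. HSPA1A and HSPA1B, adjacent and nearly identical genes of the inducible HSP70 chaperone on chromosome 6, had ratios of 0.307 (0.249 to 0.377) and 0.444 (0.423 to 0.466), and 0.435 (0.415 to 0.456) when their reads were added. The developmental genes SIX2 and LGR5 had ratios of 0.363 (0.283 to 0.462) and 0.390 (0.337 to 0.450), and the BMP pathway inhibitor gene SMAD6 had 0.426 (0.393 to 0.462). RGCC stood at 0.379, carbonic anhydrase gene CA2 at 0.409, the tropomyosin gene TPM1 at 0.437, the transcriptional coregulator gene CITED2 at 0.466 and NPTX1 at 0.477. MT-ATP6, a mitochondrially encoded subunit of ATP synthase, stood at 7262 FPKM in the control and 3687 FPKM in the exposed library, a ratio of 0.508 (0.502 to 0.514).

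**Figure D1:**
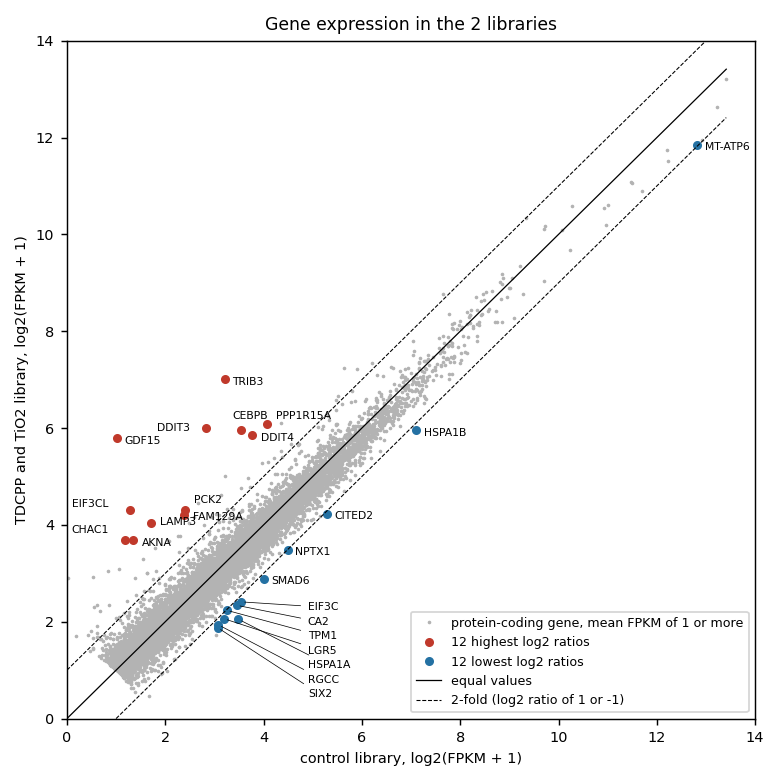
Expression of 11409 protein-coding genes in the control library (x axis) and the library exposed to TDCPP and titanium dioxide nanoparticles (y axis), both as log2(FPKM + 1), with 1 grey point per gene. The 12 highest (red) and 12 lowest (blue) log2 ratios among genes with a mean FPKM of at least 5 are named. Of these, GDF15 rises furthest from the line of equal values, at a log2 ratio of 4.78, and HSPA1A lies furthest below it, at -1.44.

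Of the 34 measured genes of the integrated stress response and unfolded protein response list, 14 were at least 2-fold higher, 25 at least 1.5-fold higher and 1 at least 1.5-fold lower. The list's median log2 ratio was 0.93, at percentile 100 of random lists, whose middle 95% ran from -0.20 to 0.01. TRIB3, DDIT3, CHAC1 and CEBPB were its 4 largest differences. Among members chosen as examples after their values were seen, ATF4, the transcription factor at the centre of the response, was 1.701-fold higher (1.64 to 1.76), from 130 to 221 FPKM. The amino acid transporter gene SLC3A2 was 3.09-fold higher (2.98 to 3.20), the serine synthesis genes PSAT1 at 2.22-fold (2.12 to 2.33) and PHGDH at 1.96-fold (1.88 to 2.04), and the mitochondrial folate enzyme gene MTHFD2 at 1.92-fold (1.83 to 2.01). XBP1 was 1.95-fold higher (1.84 to 2.06) and the endoplasmic reticulum chaperone gene HSPA5 1.49-fold (1.45 to 1.52). The chaperone genes HSP90B1 and CALR had ratios of 0.871 (0.854 to 0.887) and 0.899 (0.880 to 0.920), and SDF2L1, the 1 member at least 1.5-fold lower, 0.637 (0.553 to 0.733).

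All 26 genes of the p53 target list were measured and all 26 lay above the median of all genes. Their median log2 ratio was 0.67 (percentile 100, random lists -0.18 to 0.04), with 14 at least 1.5-fold and 4 at least 2-fold higher. These 4 were GDF15, SESN2 at 3.53-fold (3.30 to 3.79), the growth arrest gene GADD45A at 2.58-fold (2.32 to 2.88) and the death receptor gene TNFRSF10B at 2.10-fold (1.98 to 2.23). The cell cycle inhibitor gene CDKN1A and the p53 ubiquitin ligase gene MDM2, singled out after their values were seen, were 1.59-fold (1.498 to 1.697) and 1.65-fold (1.60 to 1.71) higher. SESN2 also belongs to the stress response list, and without it the median of the other 25 genes was 0.66, still at percentile 100. Only the entry shared by the 2 lists was removed. Whether the other genes were higher separately from the stress response was not tested.

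Genes that promote apoptosis did not stand apart as a list, although 4 of the 27 measured were at least 1.5-fold higher. The neuronal BH3-only gene HRK was 3.37-fold higher (2.90 to 3.93), TNFRSF10B 2.10-fold, the BH3-only gene BBC3, which encodes PUMA, 2.03-fold (1.77 to 2.32) and the death receptor gene FAS 1.86-fold (1.59 to 2.17). Cytochrome c gene CYCS was the 1 member at least 1.5-fold lower, at a ratio of 0.652 (0.622 to 0.684). The list's median log2 ratio was 0.01, at percentile 83.1. Among apoptosome genes singled out after their values were seen, APAF1 stood at a log2 ratio of -0.34 and CASP9 at 0.23. The 10 measured genes that oppose apoptosis had a median of -0.05 at percentile 57.1, and none reached 1.5-fold. In this list BAG3 stood at -0.54, the mitotic survivin gene BIRC5 at -0.42, BAG1 at -0.26 and BCL2L2 at 0.43.

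None of the 14 measured mitochondrial fission genes and none of the 17 fusion and cristae genes reached 1.5-fold in either direction. The fission list had a median log2 ratio of 0.02 (percentile 87.3, random lists -0.20 to 0.09) and the fusion list -0.12 (percentile 26.7, random lists -0.21 to 0.08). DNM1L, the dynamin-related GTPase that divides mitochondria (ENSG00000087470, chromosome 12, 32679200 to 32745650), stood at 32.6 and 30.1 FPKM, a ratio of 0.925 (0.883 to 0.969). Of its adaptors, FIS1 stood at a log2 ratio of 0.20, MFF at -0.02, MIEF1 at 0.05 and MIEF2 at 0.11. The largest fission value was that of GDAP1, a gene mutated in Charcot-Marie-Tooth neuropathy, at 1.30-fold (1.14 to 1.49), and MUL1 stood at 0.19 and SPIRE1 at 0.16 in log2 ratio. MTFR1 stood at 0.07, MARCH5 at -0.01, DNM2 at -0.05, SLC25A46 at -0.07, MTFR2 at -0.12 and INF2 at -0.14.

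Among fusion genes the outer membrane GTPase gene MFN1 (chromosome 3, 179347692 to 179394931) had a ratio of 0.791 (0.728 to 0.860), MFN2 0.896 (0.851 to 0.944) and the inner membrane GTPase gene OPA1 0.868 (0.822 to 0.916). The prohibitin gene PHB stood at 0.812 (0.766 to 0.861) and the cristae organiser IMMT at 0.820 (0.780 to 0.862). MIGA2 had a log2 ratio of -0.24, STOML2 -0.19, MINOS1 -0.15, MIGA1 -0.12, APOOL -0.09, OMA1 -0.07, PHB2 -0.05, OPA3 -0.05 and YME1L1 -0.03. CHCHD3 and CHCHD6 stood at 0.15 and PLD6 at 0.07. The sign of some small values depended on scaling: those of DNM1L, MFF, MARCH5, DNM2, SLC25A46, OMA1, PHB2, OPA3 and YME1L1 were opposite when the FPKM of each library were scaled to equal sums, a setting that moved the median of all genes by 0.11. The signs of MFF, MARCH5, DNM2, PHB2, OPA3 and YME1L1 were also opposite with scaling without the 100 most abundant and the mitochondrially encoded genes. Those of MFF, MARCH5 and YME1L1 were opposite with the trimmed mean set to 0 as well. The mitophagy list of 13 measured genes had a median of 0.07 at percentile 95.5, with SQSTM1 at 0.44, OPTN at 0.41, CALCOCO2 at 0.25 and FUNDC1 at -0.41. It stood apart as higher without a filter on low values (percentile 98.3) and with the GC and length trend removed (percentile 98.4).

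Messenger RNAs of the mitochondrial genome were lower in the exposed library, and mitochondrial ribosomal RNAs were higher. All 13 mitochondrially encoded messenger RNAs lay below the median of all genes, with a median log2 ratio of -0.60 (percentile 0, random lists -0.32 to 0.03), and the same median stood at percentile 0 among medians of random lists drawn from the 100 most abundant nuclear genes. MT-ATP6 and MT-CO3 had the lowest values, at -0.98 and -0.97, followed by MT-ND2 at -0.80 and MT-ND3 at -0.78, while MT-CO1, singled out after its value was seen, stood at -0.20. These messenger RNAs took 5.70% of control reads (5.69% to 5.71%) and 4.25% of exposed reads (4.24% to 4.26%). The 16S ribosomal RNA gene MT-RNR2 (mitochondrial genome, 1671 to 3229) was 1.79-fold higher (1.77 to 1.80) and the 12S gene MT-RNR1 1.31-fold (1.28 to 1.33).

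**Figure D2:**
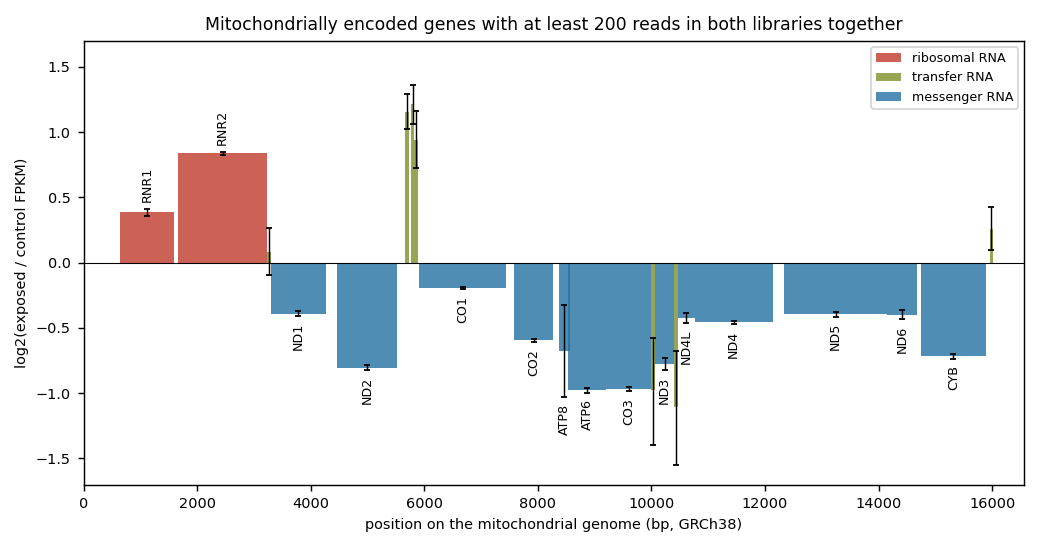
Difference between the libraries along the mitochondrial genome (x axis, position in bp on GRCh38), as log2 of the exposed over the control FPKM (y axis), for genes with at least 200 reads in both libraries together. Bars span each gene, with transfer RNAs widened to be visible where needed, and error bars are exact 95% counting intervals; ribosomal RNAs (red) lie above 0, with MT-RNR2 at 0.84, and all 13 messenger RNAs (blue) lie below it.

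Nuclear genes of the respiratory chain were lower by a smaller margin. Of 39 measured, 34 lay below the median of all genes, and the list median was -0.25 (percentile 0.305, random lists -0.20 to -0.01). The 4 members at least 1.5-fold lower were the ATP synthase c-subunit genes ATP5MC3 at -0.78 and ATP5MC1 at -0.77, CYCS at -0.60 and the complex I gene NDUFA2 at -0.60. In the mitochondrial biogenesis and stress list (15 measured, median -0.26, percentile 1.05) members went both ways. The protease gene LONP1 was 1.99-fold higher (1.88 to 2.09) and the mitochondrial HSP70 gene HSPA9 1.40-fold (1.36 to 1.44), while the chaperonin genes HSPE1 and HSPD1 stood at -0.67 and -0.38 and the mitochondrial transcription genes TFAM and POLRMT, singled out afterwards, at -0.33 and -0.30. This list no longer stood apart with a pseudocount of 5 (percentile 18.1), without a filter (4.31) or at a mean FPKM of at least 5 (8.95).

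Heat shock genes, cholesterol synthesis genes and mitotic genes were lower as groups. Of 19 heat shock protein genes 15 lay below the median of all genes, and the list median was -0.47 (percentile 0, random lists -0.25 to 0.02). Besides HSPA1A and HSPA1B, HSPA4 stood at -0.70 and HSPE1 at -0.67, and the abundant HSP90AA1 and HSPA8, singled out afterwards, at -0.55 and -0.58. Without HSPA1A and HSPA1B the median was -0.44, still at percentile 0. The cholesterol synthesis and uptake list (24 measured, median -0.35, percentile 0) held the isoprenoid enzyme gene IDI1 at -0.96, ACAT2 at -0.79 and HMGCS1 at -0.58. All 28 G2/M genes lay below the median of all genes, with a median of -0.50 (percentile 0). The mitotic kinesin gene KIF20A had a ratio of 0.499 (0.463 to 0.537), DLGAP5 0.532 (0.491 to 0.576), the proliferation marker MKI67 0.556 (0.540 to 0.574) and the mitotic cyclin gene CCNB1 0.602 (0.573 to 0.632). The G1/S list (26 measured, median -0.20, percentile 5.94) did not stand apart, with cyclin genes CCNE1 at -0.84, CCND1 at -0.74 and CCNE2 at -0.69 and RRM2 at -0.56, but did against unmatched random lists (percentile 0.460).

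Redox genes divided. In the NRF2 and glutathione list (21 measured, median -0.04, percentile 77.8) the cystine transporter gene SLC7A11 was 3.86-fold higher (3.57 to 4.17), the ferritin genes FTH1 and FTL 2.19-fold (2.12 to 2.25) and 1.998-fold (1.95 to 2.05), and haem oxygenase gene HMOX1 2.06-fold (1.79 to 2.38). The classical NRF2 targets NQO1, GCLM and TXNRD1, singled out afterwards, stood at log2 ratios of 0.02, -0.07 and -0.04, and the signs of GCLM and TXNRD1 were opposite with FPKM scaled to equal sums. Antioxidant enzyme genes (19 measured, median -0.25, percentile 1.78) were lower as a list, with GPX3 at -0.60 and PRDX1 at -0.52 but MSRB2 at 0.65 and PRDX5 at 0.59, and stood inside the random range with a pseudocount of 0.1 (percentile 3.42). The ferroptosis list (17 measured, median 0.09, percentile 98.6) shared CHAC1 and SLC7A11 with the stress response list. It shared SLC7A11, HMOX1, FTH1 and FTL with the NRF2 list, and held VDAC3 at -0.63. Without the members shared with the stress response list it had percentile 92.3, and against unmatched random lists 97.2, so it did not stand apart there. Removal of the members shared with the NRF2 list was not run.

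Immediate early genes (20 measured, median 0.30, percentile 100) were higher, with the transcription factor genes FOSL1 at 2.58-fold (2.07 to 3.23), EGR1 at 2.92-fold (2.27 to 3.80), FOSB at 4.21-fold (3.05 to 5.92) and ATF3 at 2.17-fold (1.99 to 2.36). Lysosome and autophagy genes (33 measured, median 0.13, percentile 100) were higher by a small margin, led by GPNMB at 0.85, WIPI1 at 0.63, HEXA at 0.50 and SQSTM1 at 0.44. Cytosolic ribosomal protein genes (31 measured, median 0.12, percentile 100) were higher with none at 1.5-fold, and RPS2 stood at 0.40, RPL13A at 0.33, RPLP0 at 0.32 and RPL13 at 0.29.

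Most genes that mark the noradrenergic identity of neuroblastoma cells were low or undetected in both libraries. Only 6 of the 24 listed reached a mean FPKM of 1, among them GATA2 at 11.7 and 7.03 FPKM and HAND1 at 8.92 and 6.82 FPKM. The identity factor gene PHOX2A had 0 and 0 reads, the catecholamine synthesis gene TH had 0 and 0 reads and DBH 10 and 3, and the chromogranin genes CHGA and CHGB had 2 and 0 and 4 and 4 reads. A count of 0 allows up to 3 reads, or 0.182 and 0.196 RPM (reads scaled to library size) in the control and exposed library. The neurofilament gene NEFL at 74.0 and 55.5 FPKM and UCHL1 at 201 and 237 FPKM, both singled out afterwards, were abundant, but 11 of the 22 listed neuronal cytoskeleton and outgrowth genes were not measured, among them TUBB3 with 6 and 7 reads and STMN2, INA and ELAVL4 with 0 and 0. The 6 measured noradrenergic genes had a median log2 ratio of -0.35 (percentile 0.220), with GATA2 at -0.66, ISL1 at -0.48, TBX2 at -0.35 and HAND1 at -0.34.

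The mesenchymal identity list (19 measured, median -0.27, percentile 0.05) was lower, with the collagen gene COL3A1 at -0.96, CTGF at -0.93 and THBS1 at -0.77 but FOSL1 at 1.17, and did not stand apart at a mean FPKM of at least 5 (percentile 4.41). Of the fibroblast genes LUM had a ratio of 0.320 (0.221 to 0.456), and COL3A1 and COL1A1 log2 ratios of -0.96 and -0.61 (3 measured, median -0.96, percentile 0), all at 6.24 FPKM or less in either library. The epithelial keratin genes KRT8 at 325 and 223 FPKM, KRT18 at 255 and 162 FPKM and KRT19 at 39.3 and 25.7 FPKM were abundant and lower in the exposed library (3 measured, median -0.60, percentile 0.340). That list stood at percentile 11.2 without a filter on low values. Its other members were not measured, among them EPCAM with 3 and 5 reads and CDH1 with 4 and 10. None of the 12 myeloid and lymphoid genes and none of the 12 erythroid and hepatocyte genes was measured, and their highest mean values were 0.860 and 0.418 FPKM.

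The other lists lay inside the random range, with single members that differed. In the glycolysis and hypoxia list (27 measured, median -0.10, percentile 40.8) the angiogenic factor gene VEGFA was 4.24-fold higher (3.87 to 4.65), BHLHE40 stood at 1.07, NDRG1 at 0.77 and ALDOC at -0.82. In the inflammation and NF-kB list (11 measured, median 0.12, percentile 92.3) CXCL8 was 5.29-fold higher (3.21 to 9.15), from 0.522 to 2.76 FPKM, RELB stood at 0.95, NFKB2 at 0.41 and CCL2 at -0.79, and this list stood apart as higher without a filter on low values (percentile 99.98). Interferon genes (12 measured, median -0.18, percentile 3.37) held IFIT1 at -0.76, IFI6 at -0.49, IRF1 at 0.41 and IRF7 at -0.38, and stood apart as lower with a pseudocount of 0.1 (percentile 2.43). Replication-dependent histone genes (8 measured, median 0.10, percentile 85.9) held HIST1H2AC at 0.97, HIST2H2BE at 0.72, HIST1H2AG at 0.64 and HIST1H1C at -0.25. DNA repair genes (27 measured, median -0.06, percentile 59.1) held XRCC5 at -0.48, XRCC6 at -0.46 and RAD51C at 0.44.

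Metallothionein and metal response genes, of interest for a metal oxide particle, had a median of 0.08 over 5 measured members (percentile 84.6), with MT1X at 0.16, MT2A at 0.12, MT1F at 0.08 and the metal-sensing factor gene MTF1 at -0.26. Endocytosis and particle uptake genes (19 measured, median -0.18, percentile 9.35) held the caveolar genes CAV1 and CAV2 at -0.64 and CAVIN1 at -0.50, and the receptor gene SCARB1 at -0.51. Xenobiotic metabolism genes (12 measured, median -0.08, percentile 24.4) held ABCB1 at -0.46, CYP1A1 at 0.31, PON2 at -0.30 and CYP2J2 at -0.24. The nuclear receptor and hormone axis list (11 measured, median -0.13, percentile 9.32) held the glucocorticoid-induced gene TSC22D3 at 0.96, NR3C2 and the thyroid hormone receptor gene THRA at -0.34, and CYP26B1 at -0.29. Fatty acid and lipid droplet genes (22 measured, median -0.06, percentile 47.7) held MYLIP at -0.90, PLIN3 at -0.57, ACLY at -0.56 and ELOVL6 at -0.52.

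Among neuronal lists, cytoskeleton and outgrowth genes (11 measured, median -0.11, percentile 26.8) held the microtubule-associated genes MAP2 at 0.82 and MAP1B at 0.76, DPYSL2 at 0.49 and the tubulin gene TUBA1A at -0.71. Synapse genes (13 measured, median -0.04, percentile 40.8) held SYT1 at 0.47, PCLO at 0.43, NLGN2 at -0.41 and VAMP2 at 0.39. Neurodegeneration genes (17 measured, median 0.03, percentile 91.0) held SOD1 at -0.52, TARDBP at -0.38 and PSEN2 and BACE1 at 0.26, and neurotrophin signalling genes (8 measured, median -0.04, percentile 41.6) NRTN at -0.34, SORT1 at -0.30, NTF3 at -0.28 and NGFR at 0.25. Ion channel and calcium genes (19 measured, median -0.11, percentile 27.0) held the mitochondrial porin genes VDAC3 at -0.63 and VDAC1 at -0.58, the calcium sensor gene STIM1 at 0.47 and CAMK2G at -0.38. Extracellular matrix and adhesion genes (23 measured, median -0.10, percentile 31.5) held MMP14 at 0.41, LAMB1 and TIMP2 at -0.38 and FN1 at -0.37.

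**Figure D3:**
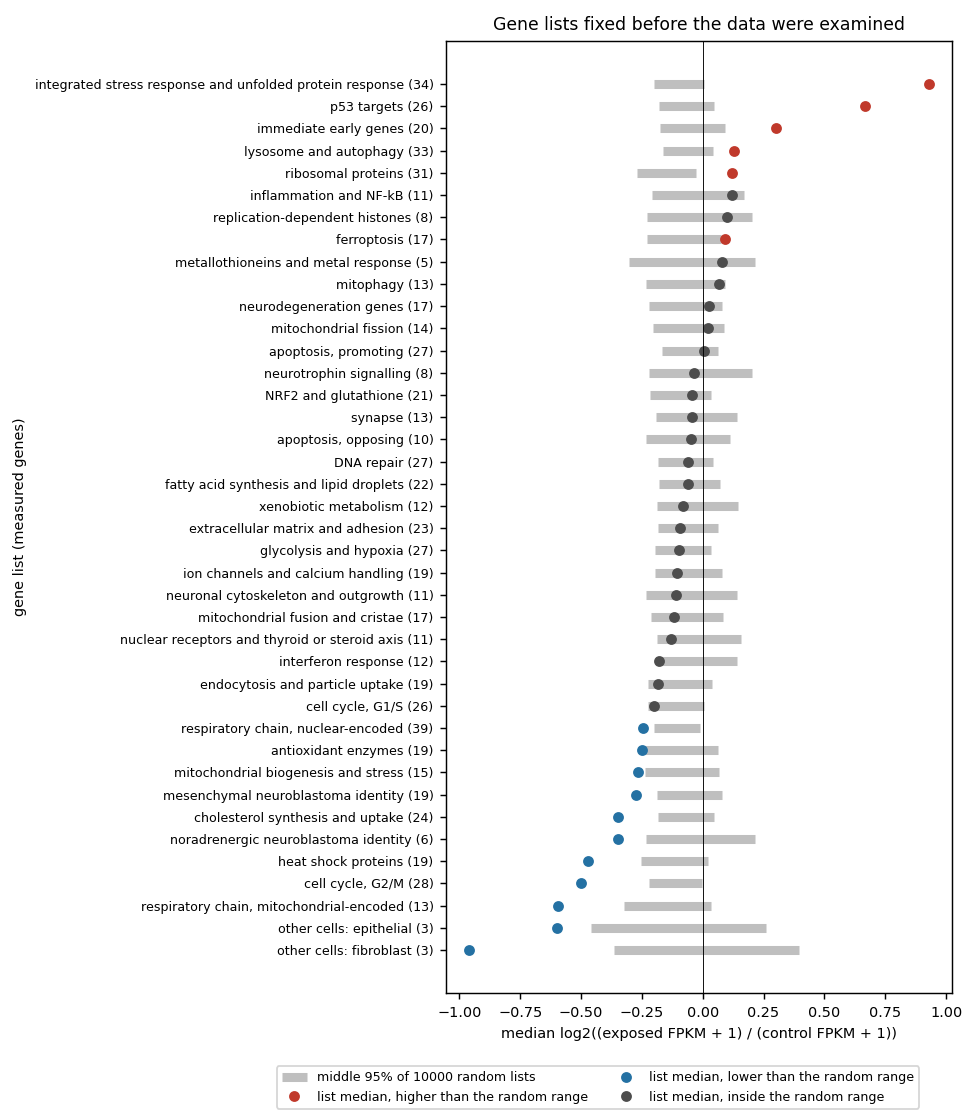
Median log2((exposed FPKM + 1)/(control FPKM + 1)) of the 40 gene lists with at least 3 measured genes (points, number of measured genes in brackets), with the middle 95% of 10000 random lists of matched expression (grey bars). The 6 red points lie above and the 11 blue points below their bars, the stress response list is highest at 0.93, and the fission and fusion lists lie inside theirs at 0.02 and -0.12.

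In all, 6 of the 40 lists with a percentile stood apart as higher and 11 as lower, where chance alone would give 2, and 23 lay inside. Because genes of a list move together, such a count describes these libraries and does not measure how often cultures would differ this much.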

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

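The tests of RNA without a poly(A) tail, sequencing depth and a difference between cultures were chosen after the results were seen.

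Of the genes of other classes, the 5 described here were at least 2-fold higher with a mean FPKM of at least 5 and at least 100 control reads, a choice that leaves out the genes that were lower and those with fewer reads. The long noncoding RNA NEAT1, which builds nuclear paraspeckles, stood at 24.5 FPKM in the control and 60.6 FPKM in the exposed library, a ratio of 2.48 (2.42 to 2.54). NBR2, transcribed from the promoter region it shares with its neighbour, stood at 3.43 and 13.6 FPKM, a ratio of 3.98 (3.23 to 4.93). The processed pseudogene DHFRP1 stood at 39.0 and 101 FPKM. The mitochondrial transfer RNA genes MT-TN and MT-TC, close neighbours on the light strand, stood at 596 and 1329 FPKM and at 512 and 1188 FPKM. Other mitochondrial transfer RNA genes went both ways, with MT-TY at a ratio of 1.92 (1.65 to 2.23) and MT-TG at 0.507 (0.381 to 0.671). Mitochondrial ribosomal RNA took 0.757% of control reads (Wilson 95% interval 0.753% to 0.761%) and 1.37% of exposed reads (1.368% to 1.38%).

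Genes of the integrated stress response stood higher as a list, with a median log2 ratio of 0.93. Removal of a trend on GC content and gene length left the median at 0.92, which argues against such a trend as the whole cause. Scaling without the 100 most abundant and the mitochondrially encoded genes gave 1.001. A change of scaling moves all genes by nearly the same amount, here 0.06 for the median of all genes. It therefore bears on the level of the list and could not alter its place among random lists. A difference between the cultures unrelated to the exposure and a response to the mixture cannot be told apart with 1 control library. Neither agent alone was measured here, so the share of each also stays open.

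Mitochondrial messenger RNAs were lower while mitochondrial ribosomal RNAs were higher. Pooled nuclear small RNAs had 3008 and 2884 reads, a ratio of 0.973 (0.924 to 1.02), so these classes did not differ beyond counting error. Few reads fell on them, and some may come from overlapping genes. They therefore cannot decide whether the exposed library held a larger share of RNA without a poly(A) tail. Such a larger share stays open as a cause. Of 8 measured replication-dependent histone genes, whose messenger RNAs largely lack that tail, 3 were at least 1.5-fold higher. These were HIST1H2AC, HIST2H2BE and HIST1H2AG, and the list median of 0.10 lay inside the random range. A candidate explanation that stays open is altered processing or turnover of mitochondrial transcripts, for which no test was run. A difference between 2 cultures that is not the exposure stays open too, with 1 control library.

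Most genes that mark the noradrenergic state were low or absent in both libraries, including the control, and 6 of 24 reached a mean FPKM of 1. Too little depth is argued against by 11409 protein-coding genes at a mean FPKM of at least 1. A shift from the noradrenergic to the mesenchymal state of the same line stays open, since 9 of 24 mesenchymal genes had a mean FPKM of at least 10. RNA of another cell line than the label says stays open too, and of such lines only an embryonic kidney origin was tested. For it 7 of 12 listed genes reached a mean FPKM of 1, which meets the bound of 6 set before they were looked up. However, 11409 of the 16515 protein-coding genes with any read reached it too. The bound is therefore met too easily to decide, and an embryonic kidney origin stays open. The highest of the 12 listed genes was HOXD11 at 6.82, PAX2 and PAX8 were under 1, and the values identify no line.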

How the results depend on the processing

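The GC and length trend and the removal of shared list members were chosen after the data were seen. Against 75 genes at least 2-fold higher and 15 lower, a pseudocount of 0.1 gave 132 and 54 and a pseudocount of 5 gave 38 and 1 (HSPA1B), since the pseudocount sets how far low values can move. A mean FPKM of at least 5 left 47 higher, with fewer genes counted. All gene classes gave 243 and 173, 1.5-fold gave 289 and 247, and 3-fold gave 25 and 0. The other settings gave 78 to 107 higher and 11 to 17 lower. Between 5 and 8 lists stood apart as higher and between 8 and 12 as lower, and no direction called for a list was reversed. Of 484 alternative list medians 471 kept their call. Of 1950 alternative values of single genes 1631 stayed inside the counting interval of the gene, and equal FPKM sums moved the most, 114. The fission, fusion and both apoptosis lists stayed inside the random range in every setting run. Without genes of the fibroblast list the mesenchymal list kept a median of -0.24 (percentile 0.560), and immediate early genes without the member shared with the stress response list kept 0.27. No paired analysis was possible because each group has 1 library, and for the same reason no setting left out a library and no model with a variance was fitted. Depth limits genes near the floor of 3 reads.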

Other observations

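The 8 lists below were all drawn up after the data were seen. Tubulin and actin genes were lower in the exposed library. All 10 measured tubulin genes lay below the median of all genes, with a list median log2 ratio of -0.66 (percentile 0), and TUBB4B stood at -0.83, TUBB at -0.67 and TUBA1B at -0.65. All 19 measured actin cytoskeleton genes did so too (median -0.36, percentile 0.02), with the cytoplasmic actin gene ACTB at 835 and 523 FPKM, ACTG1 at -0.56, CNN2 at -0.90 and TPM1 at -1.01. Targets of the mechanosensitive coactivator YAP (16 measured, median -0.42, percentile 0) held CTGF at -0.93, ANKRD1 at -0.67 and CYR61 at -0.63. CTGF and CYR61 also belong to the mesenchymal list. Of the 16 targets, 6 lay above the median of all genes, among them F3 at 0.22 and NUAK2 at 0.19.

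Cytosolic aminoacyl-tRNA synthetase genes, several of them ATF4 targets, were higher as a list (20 measured, median 0.17, percentile 100), with WARS at 1.17, SARS at 1.11, AARS at 0.89 and GARS at 0.88 but RARS at -0.43. Their mitochondrial counterparts were inside the random range (16 measured, median -0.09, percentile 30.7), with IARS2 at -0.63, as were mitochondrial ribosomal protein genes (26 measured, median -0.12, percentile 30.7), where MRPL10 stood at 0.29. Proteasome genes, of both the core and the regulatory particle (20 measured, median -0.23, percentile 6.56), held PSMD1 at -0.53. The 7 measured embryonic kidney genes had a median of -0.03 (percentile 42.2).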
